A study of Mus musculus with 6 samples.

How the data were processed

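Total RNA from 6 samples of Mus musculus cells was hybridised to 1-colour Affymetrix Mouse Gene ST arrays, 1 array per sample. RNA was extracted with Trizol and cleaned on columns, per the labels' protocols. The deposited values are log2 expression values, 1 per probe set and array, for 35556 probe sets. They were made with RMA, with the mouse build mm9, per the submitters' processing notes. The software that ran RMA and its version are not given in the sources used here. RMA corrects the background, sets the probe distributions of all arrays equal and summarises the probes of each transcript on the log2 scale, which compresses large differences and leaves no detection call. The log2 scale was read from the deposited values, which lie between 3.04 and 14.88, with array medians from 7.45 to 7.58. No column was left unmapped to a sample. No scanner files, scan dates or batches were used here, so no batch could be tested.

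Groups were taken from the sample titles: 3 osteoblast samples (KUSA4b10 cells) and 3 osteosarcoma lines. Replicate numbers do not pair samples across the groups. No 2 arrays held the same values: at most 24 of 35556 probe sets had an identical value on a pair of arrays.

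Probe sets were named from the platform annotation. Of the 35556 probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 were not listed. Only probe sets with 1 symbol were used as genes. Symbols were looked up by gene identifier in the RefSeq gene table of assembly GRCm38.p6, where 21698 were found and 91 were not, and no symbol changed. No coordinates were used from that table, and only the order of neighbouring genes was taken from it. For the 999 genes with several probe sets, the probe set with the highest mean over all 6 arrays was used, which left 19938 genes. Probe sets of a named gene differed in size, but not in direction, for Cd80, Idi1, Loxl4, Nlrc5, Tet1 and Ighm.

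The groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with default settings), two-sided, on the deposited log2 values without further normalisation, filter or covariate. Differences are osteosarcoma minus osteoblast on the log2 scale, and folds are their powers of 2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 19938 genes. All 6 arrays entered each fit. The 30 gene lists were written, with their members, before the data were examined. They were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 30 lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, were alternatives. For Wif1 an exact permutation test was added. The smallest p of that test is 0.1. For the spread among lines, the SD of each gene over the 3 lines was compared with that over the 3 cultures, without a test.

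The genes named in the text were chosen by a rule fixed before the data were examined. It takes Wif1, Rb1, Trp53 and Sp7. It takes the 10 genes with the largest rise and the 10 with the largest fall among those called, with groups that do not overlap and a higher group mean above 7.53, the median of all values. Predicted genes and symbols of olfactory, vomeronasal, microRNA and small nucleolar RNA genes are left out. From each list it takes up to 4 called members with the largest change, or, where fewer than 2 pass, the 2 with the largest difference as values. For each line it takes the 3 genes furthest above and the 3 furthest below the other 2 lines, where those differ by less than 0.5. Col1a1, Col1a2, Sparc, Cdh11, Pdpn, Capg, Fabp5 and Axin2 are named outside the rule, after their values were seen. So are the genes of the closing observations that the rule does not give.

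The fit was tested on simulated data with the mean and residual SD of each gene on these arrays. The SD was the same in both groups. Of the 19938 genes, 200 were changed, all with a mean above the median of all values. It recovered 72% of 100 genes changed 2-fold and 93% of 100 genes changed 4-fold. Of 173 calls, 8 were false (4.62%), and none had the wrong direction. A simulated list of 20 shifted genes was called, and 0 of 30 lists without a shift were called. The simulation draws genes independently, so it does not test lists of correlated genes. In the real arrays the median SD over lines was 1.42 times that over cultures, and 24.6% of genes were called. The simulated recovery and share of false calls therefore need not hold for these arrays.

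Alternatives were quantile normalisation, median centring, a filter to genes whose higher group mean is above the median of all values, an intensity trend, robust moderation, a spread of its own for each group, array weights, the mean of a gene's probe sets, all probe sets by identifier, at least a 2-fold change, adjusted p under 0.01, lists without replication and mitosis genes, and leaving out each array in turn. The mean of osteoblast cultures 1 and 3 taken as 1 sample was added after seeing the data. Array quality beyond these values was not analysed here. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.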

Results

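Gene expression was measured in 3 mouse osteosarcoma cell lines and in 3 samples of cultured mouse osteoblasts, with 1 Affymetrix Mouse Gene ST array per sample and 6 arrays in all. The osteosarcoma lines, OS_493H, OS_494H and OS_716H, came from primary bone tumours of C57Bl6 mice in which Cre recombinase, expressed from the Osterix (Sp7) promoter of the osteoblast lineage, acts on floxed p53 and Rb alleles. Per the labels, OS_493H came from a hip tumour of a female, OS_494H from a hip tumour of a male and OS_716H from a tibial tumour of a female, at ages of 188, 190 and 226 (unit not given). The osteoblasts were KUSA4b10 cells, a mouse bone marrow stromal line, differentiated in medium with 50 ug/ml ascorbate for 21 days after reaching confluence. These 3 samples are called osteoblast cultures 1 to 3 below. Their titles number them as replicates 1 to 3 and as Ex1 to Ex3, which is not explained and does not settle whether they were grown as separate experiments. If they were not, the spread between these samples may in part be technical. It enters the p-values together with the spread between the lines. In either case all 3 are 1 cell line, so p-values do not cover the spread between osteoblast lines. Values are log2 expression, and 19938 genes were tested. The number of arrays, 3 per group, limits the precision of every value. The labels give no differentiation day or ascorbate for the lines, so tumour origin cannot be told apart from growth and differentiation state.

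The arrays separated by group. The first principal component held 73.0% of the variance and placed the 3 cultures on one side (scores -46.13, -35.37 and -45.91) and the 3 lines on the other (41.55, 45.82 and 40.05). Across genes, which are not independent replicates, Pearson's r was 0.981 to 0.987 between osteosarcoma lines and 0.948 to 0.961 between a line and a culture. Osteoblast cultures 1 and 3 were closer to each other (r = 0.998, with 3 genes differing by more than 1 log2 unit) than to culture 2 (150 and 186 genes).

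Rb1, the retinoblastoma tumour suppressor and a gene targeted in the mouse model, was lower in the osteosarcoma lines, at 9.61 ± 0.32 (SD, n = 3) against 10.67 ± 0.01 (SD, n = 3) in the osteoblast cultures, a log2 difference of -1.05 ± 0.15 (SE, limma adjusted p = 0.00427). Each line lay below each culture, with values of 9.26 in OS_493H, 9.70 in OS_494H and 9.87 in OS_716H. The value averages probes along the transcript, including exons outside the deleted part, so it is not a measure of allele loss. Trp53 was not analysed here. Sp7, the osteoblast transcription factor whose promoter drives Cre, was 7.64, 8.25 and 9.04 in the 3 lines and 9.13, 10.50 and 8.91 in the 3 cultures. Its difference of -1.21 did not pass the test (adjusted p = 0.141), and the groups overlapped. Sex-linked transcripts were compared with the labelled sex. Xist, the RNA that coats the inactive X chromosome, was 12.62 in OS_493H, 5.31 in OS_494H and 5.50 in OS_716H. The Y-linked genes Eif2s3y, Uty and Kdm5d were at 4.08, 5.11 and 5.42 in OS_493H, but at 9.96, 9.90 and 8.85 in OS_494H and at 10.11, 10.06 and 8.92 in OS_716H. The array labelled OS_716H, a female, therefore carried Y-linked transcripts at the level of the male line and no Xist signal above that of the cultures.

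The series title names Wif1, a secreted inhibitor of Wnt signalling, and asks of it whether methylation silences the gene in osteosarcoma or whether its level follows the stage of osteoblast differentiation. Methylation was not analysed here. Wif1 expression was 6.68 in OS_493H, 6.74 in OS_494H and 7.66 in OS_716H, with a mean of 7.03 ± 0.55 (SD, n = 3), against 8.09, 10.11 and 8.14 in osteoblast cultures 1, 2 and 3, with a mean of 8.78 ± 1.15 (SD, n = 3). All 3 lines lay below all 3 cultures. The log2 difference was -1.75 ± 0.58 (SE), a 3.37-fold lower level. It did not pass the threshold across all genes (limma adjusted p = 0.073), and a two-sided exact permutation test gave p = 0.1, the smallest value that 3 samples against 3 allow. Culture 2 lay 2.00 log2 units above the mean of cultures 1 and 3, and without it the difference was -1.09 (adjusted p = 0.0682). Over all alternative settings the adjusted p was 0.0551 to 0.184. Among all genes Wif1 had the rank 199 by size of fall.

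**Figure D1:**
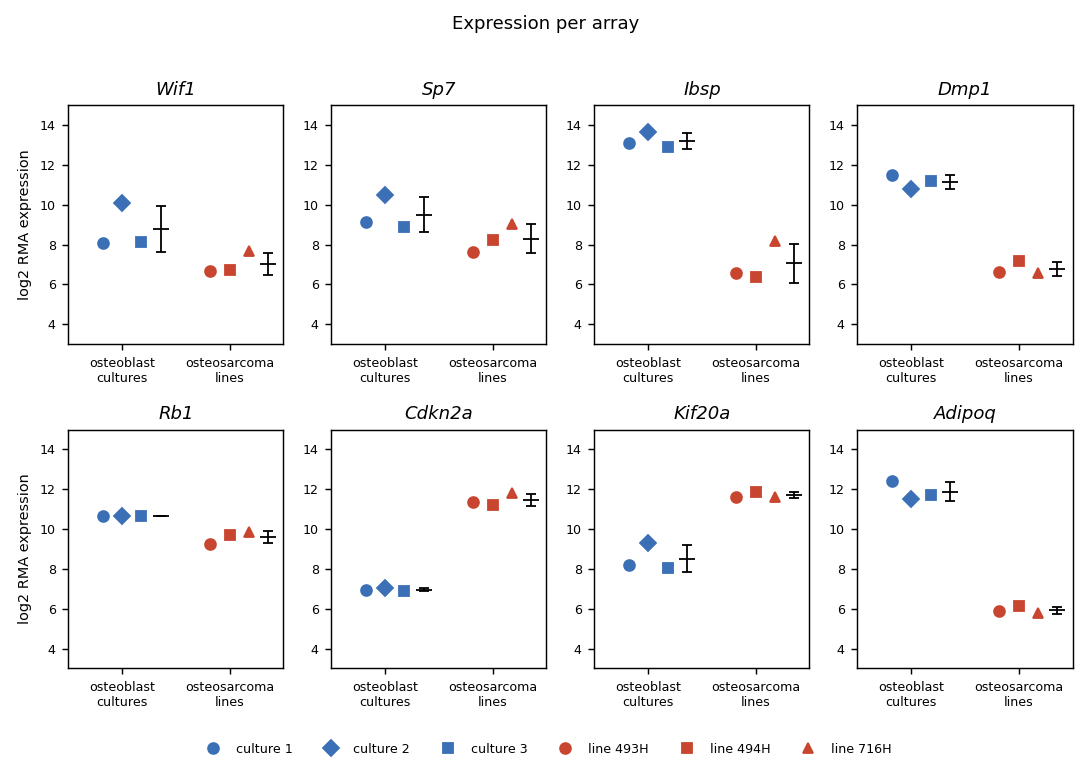
Log2 expression of 8 genes on each of the 6 arrays, with osteoblast cultures in blue, osteosarcoma lines in red, and the mean and SD of each group as bars with whiskers (n = 3). Wif1 and Sp7 are spread widely within the groups, with culture 2 highest at 10.11 and 10.50, whereas the group means of Ibsp, Dmp1, Adipoq, Cdkn2a and Kif20a differ by -6.16, -4.36, -5.95, 4.52 and 3.19 log2 units.

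Over all genes, 2622 were higher and 2274 were lower in the osteosarcoma lines than in the osteoblast cultures (limma, Benjamini-Hochberg adjusted p under 0.05). At least a 2-fold change was found for 811 of the higher and 561 of the lower genes. The groups did not overlap for 41.5% of all genes, against 10% by chance. Among the largest falls, Car3, a carbonic anhydrase abundant in fat and muscle, was 140.4-fold lower, at 6.76 ± 0.41 (SD, n = 3) in the lines and 13.90 ± 0.11 (SD, n = 3) in the cultures, a log2 difference of -7.13 ± 0.20 (SE, adjusted p = 8.97e-05). Ibsp, which encodes bone sialoprotein, was 71.5-fold lower (-6.16 ± 0.48, adjusted p = 7.14e-04). Adiponectin (Adipoq), the fatty acid transporter Cd36 and resistin (Retn) were lower by 61.6-, 37.5- and 27.0-fold. Lumican (Lum), a small leucine-rich proteoglycan of collagen matrix, and Phex, an endopeptidase of osteoblasts and osteocytes that affects mineralisation, were lower by 27.2- and 26.6-fold. Serglycin (Srgn), insulin-like growth factor 2 (Igf2) and glycerol-3-phosphate dehydrogenase (Gpd1) completed the 10 largest falls, at 25.5-, 22.7- and 22.1-fold.

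Among the largest rises, calponin 1 (Cnn1), an actin-binding protein of smooth muscle, was 28.1-fold higher in the lines (log2 difference 4.81 ± 0.44 SE, adjusted p = 0.00106). Thy1, a surface glycoprotein of stromal cells and thymocytes, was 26.2-fold higher, at 11.91 ± 0.68 against 7.20 ± 0.10 (SD, n = 3 each). Cdkn2a, which encodes the p16INK4a and p19ARF tumour suppressors, was 22.9-fold higher, with values of 11.37, 11.23 and 11.82 in the 3 lines and 6.93, 7.04 and 6.90 in the 3 cultures (4.52 ± 0.16, adjusted p = 1.06e-04). Arhgdib and Cd34 were higher by 20.3- and 19.7-fold. Neto2, Atp1b1 (a sodium pump subunit), Igfbp6, the coagulation inhibitor Tfpi and the microfibril protein Mfap5 were higher by 15.5- to 17.9-fold. Each of the 10 largest rises and 10 largest falls kept its call when any 1 array was left out. These genes were picked from the same arrays for large, called differences, which favours keeping the call. The total counts fell to 1533 higher and 1211 lower without osteoblast culture 1, and to 1610 and 1350 without culture 3.

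Among the 30 gene lists fixed before the data were examined, 9 passed a competitive test with a preset correlation of 0.01 between genes (limma camera), 5 upward and 4 downward. With the correlation estimated from the data none passed (smallest adjusted p = 0.444). The lists lost included some with an estimated correlation near the preset, such as inhibitors of cyclin-dependent kinases (-0.05) and mature osteoblast markers (0.02). Other splits of the same 6 arrays called no gene, but up to 10 lists at the preset correlation. Each of those splits mixes the groups and keeps part of their difference, so these counts do not show what chance gives. Fry, a test of each list without comparison to other genes, called 10 lists. It lost the beta-catenin, interferon and imprinted lists and added those of p53 targets (adjusted p = 0.0164) and of the DNA methylation machinery, stromal progenitor and endothelial markers (0.00594 each). The counts of changed members below come from the gene-level test over all genes. Adjusted over the list alone, the counts were identical for 21 of the 30 lists, and the others are given where they occur.

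Osteoblast genes were divided. Of 20 measured markers of mature osteoblasts and osteocytes, 10 fell and 3 rose in the lines (camera adjusted p = 0.0166, and adjusted p = 0.444 with an estimated correlation). Besides Car3 and Phex, Dmp1, a matrix phosphoprotein of osteocytes, was 20.6-fold lower (6.80 ± 0.35 against 11.16 ± 0.35, SD, n = 3 each), and Phospho1, a phosphatase of matrix vesicles, was 10.9-fold lower. The members that rose were Cdh11, Pdpn and Capg. Of 13 measured markers of early osteoblasts and type I collagen, 4 fell and none rose, and the list did not pass (adjusted p = 0.112), though it did after median centring (0.039), without culture 3 (0.0487) and without OS_716H (0.0359). Ibsp and the homeobox gene Dlx3 (-1.19 ± 0.07 SE, adjusted p = 3.36e-04) fell, and so did Bmp4 (-0.96, adjusted p = 0.0242) and the parathyroid hormone receptor Pth1r (-1.71, adjusted p = 0.0497). The last 2 calls were lost on leaving out any 1 array except OS_716H (adjusted p up to 0.071 for Bmp4 and 0.14 for Pth1r). The collagen genes Col1a1 and Col1a2 and the matrix protein Sparc differed by -0.07, -0.03 and -0.04, none past the threshold. Fat cell markers moved with the osteoblast lists, and Car3 is expressed in fat as well. Of 17 measured adipocyte markers, 15 fell and 1 rose (camera adjusted p = 2.95e-10, and adjusted p = 0.444 with an estimated correlation). Adjusted over the list alone, 16 fell. In the cultures Adipoq averaged 11.88 ± 0.48, Retn 11.92 ± 0.31 and the lipid droplet protein Plin1 10.51 ± 0.49 (SD, n = 3 each), and in the lines they averaged 5.93, 7.16 and 7.27. The member that rose was Fabp5 (1.92 ± 0.24 SE). On leaving out 1 array, 13 to 15 adipocyte markers fell. Without culture 1 or without line OS_493H, 6 mature osteoblast markers fell. With any 1 array except OS_716H left out, 2 early markers fell.

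Proliferation genes rose almost without exception. The cultures were taken 21 days after confluence, so this rise cannot be told apart from a difference in growth state. All 30 measured mitosis genes were higher in the lines, with a median log2 difference of 2.45 (camera adjusted p = 1.48e-19, and adjusted p = 0.446 with an estimated correlation). The mitotic kinesin Kif20a rose 9.12-fold (11.70 ± 0.16 against 8.51 ± 0.67, SD, n = 3 each), the checkpoint kinase Bub1b 7.99-fold, and the kinetochore genes Nuf2 and Cenpe 7.87- and 7.75-fold. Of 34 measured E2F and DNA replication genes, 33 rose and none fell (median 1.60, camera adjusted p = 2.22e-20, and adjusted p = 0.444 with an estimated correlation), among them the ribonucleotide reductase subunit Rrm2 at 6.33-fold, the DNA polymerase Pole at 6.18-fold, the helicase subunit Mcm6 at 4.49-fold and the primase Prim1 at 4.43-fold. Of 8 measured inhibitors of cyclin-dependent kinases and related genes, 5 rose and 1 fell (camera adjusted p = 0.019, and adjusted p = 0.444 with an estimated correlation). Cdkn2a rose most, Cdkn2b rose 2.53-fold and Cdkn3, a phosphatase gene that itself rises in dividing cells, 6.67-fold. Rbl2, which encodes the Rb relative p130, fell 1.76-fold. When only brighter genes were tested this list did not pass (adjusted p = 0.0836). Of 29 measured p53 target genes, 11 fell and 3 rose (camera adjusted p = 0.0507). Cd80, Trp53inp1 and Eda2r fell 15.1-, 4.74- and 4.41-fold, and a further Cd80 probe set gave a smaller log2 difference of -2.32 (adjusted p = 6.63e-04 over all probe sets). Ckap2, a spindle protein, rose 4.25-fold. The p53 list passed under some other settings, among them quantile normalisation (adjusted p = 0.013), without OS_493H (0.00617), without OS_494H (0.0468) and without culture 1 (0.0327), and 1 member rose on leaving out any 1 culture.

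Cholesterol synthesis genes were higher as a group. Of 20 measured members, 18 rose and none fell, with a median log2 difference of 1.57 (camera adjusted p = 1.26e-12, and adjusted p = 0.444 with an estimated correlation). Idi1, the isopentenyl diphosphate isomerase, rose 8.72-fold, the sterol transfer protein Stard4 7.85-fold, the demethylase Cyp51 5.02-fold and the synthase Hmgcs1 3.96-fold. The hypoxia and glycolysis list did not pass (adjusted p = 0.112). Of its 22 measured members, 11 rose and 4 fell, and 5 fell adjusted over the list alone. The prolyl hydroxylase Egln3, the aldolase Aldoc and the kinase Pdk1 rose 4.22-, 3.42- and 2.30-fold, and Vegfa fell 2.26-fold. Without culture 1 or culture 3, 4 members rose, and without OS_493H or OS_494H, 6 rose, and without culture 2 the list passed (adjusted p = 0.0445). The call of Aldoc was lost without culture 1 or culture 3 (adjusted p up to 0.0579), and that of Pdk1 on leaving out any 1 array except culture 2 (up to 0.113).

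Wnt pathway genes went in both directions. Of 18 measured secreted antagonists, Sfrp2 rose (1.70 ± 0.37 SE, adjusted p = 0.0169), Dkk1 and Sost fell (-0.80 and -0.46), and 15 did not pass, Wif1 among them. The calls of Sfrp2, Dkk1 and Sost were each lost without culture 1 (adjusted p = 0.0634, 0.0654 and 0.0514). That of Sfrp2 was also lost without culture 3 (0.0669), that of Dkk1 without culture 2 (0.0673) and those of Dkk1 and Sost without OS_493H (0.0591 and 0.0616). Without OS_494H, 4 antagonists rose. The list as a whole did not pass (adjusted p = 0.797), and its median (-0.10) and mean (0.02) differed in sign. Of 19 ligands, Wnt5a, a ligand of non-canonical signalling, rose 5.17-fold, at 9.19 ± 0.45 against 6.82 ± 0.06 (SD, n = 3 each), and the list did not pass (adjusted p = 0.834). Wnt16 was 8.59, 6.91 and 8.15 in the lines against a culture mean of 6.99. Of 20 receptors, 7 rose and 6 fell (adjusted p = 0.721), or 8 and 7 adjusted over the list alone. Fzd3, Fzd2 and Ror2 rose 3.08-, 2.99- and 2.60-fold. Lgr5, which is also on the beta-catenin list, fell 2.70-fold, a call lost without culture 1 (adjusted p = 0.0562) or OS_716H (0.0559). Receptors that fell numbered 3 without culture 1 and 4 without culture 2, and 2 ligands rose on leaving out any 1 line, with 1 lower without OS_716H. Of 21 measured beta-catenin target genes, 8 fell and none rose (camera adjusted p = 0.038, and adjusted p = 0.728 with an estimated correlation), or 9 and 1 adjusted over the list alone. Nkd2, a feedback inhibitor, and Dusp4 fell 4.40- and 2.77-fold, and Tnfrsf19 fell 4.15-fold. Axin2, a widely used target gene, differed by -0.04 and did not pass. The list's call was lost without culture 2 (adjusted p = 0.0678), without OS_494H (0.0692), without OS_716H (0.0585), with array weights (0.118) and with fry (0.0705). Without culture 1 or OS_493H, 5 members fell, and without OS_493H or OS_494H 1 rose. Without OS_493H the call of Tnfrsf19 was lost (adjusted p = 0.0583).

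Matrix and growth factor lists did not pass as groups, while single members changed strongly. Of 35 collagens and matrix proteins, 8 rose and 7 fell (adjusted p = 0.797), or 8 and 8 adjusted over the list alone. Fibrillin 2 (Fbn2) and fibulin 1 (Fbln1) rose 13.3- and 4.97-fold, and Lum and decorin (Dcn) fell 27.2- and 10.4-fold. Of 26 matrix crosslinking enzymes and proteases, 6 rose and 7 fell (adjusted p = 0.797), or 6 and 8 adjusted over the list alone, with P4ha3 and Loxl3 3.68- and 2.64-fold higher and Mmp11 and Loxl4 6.02- and 3.08-fold lower. This list's median was 0.10 and its mean -0.10. Of 31 BMP and TGF-beta pathway genes, 8 rose and 5 fell (adjusted p = 0.206), or 8 and 6 adjusted over the list alone. Id2 and Id3, inhibitors of helix-loop-helix transcription factors, rose 8.16- and 3.26-fold, the receptor Bmpr1b rose 3.06-fold, and Tgfb1 fell 3.65-fold. Of 12 osteoclast regulators, 1 rose and 2 fell (adjusted p = 0.974). Tnfrsf11b (osteoprotegerin) and Sema3a fell 5.78- and 2.59-fold, and the chemokine Ccl2 rose 2.60-fold. Of 13 complement genes, Serping1 and C2 rose 9.37- and 5.34-fold (list adjusted p = 0.112). Several of these counts changed by more than 1.5 times when 1 array was left out. Collagens and matrix proteins that rose numbered 3 without culture 1 or culture 3, 4 without OS_493H, 5 without OS_716H and 11 without culture 2. Crosslinking enzymes and proteases that fell numbered 3 without culture 2 or culture 3 and 4 without culture 1, and those that rose numbered 3 without culture 1. BMP and TGF-beta genes that fell numbered 2 on leaving out any 1 culture or OS_494H and 3 without OS_493H. Osteoclast regulators that rose numbered 2 without OS_494H and 0 on leaving out any 1 culture or OS_716H, and 1 fell without culture 1 or culture 3. Without OS_494H, 5 complement genes rose and the complement list passed (adjusted p = 0.00439). The calls of Fbln1, P4ha3, Sema3a and Ccl2 were lost without culture 1 or culture 3 (adjusted p up to 0.0707, 0.0599, 0.0546 and 0.0665), those of Fbln1, P4ha3 and Ccl2 also without OS_493H (0.0551, 0.0501 and 0.107), and that of Ccl2 also without culture 2 (0.057) or OS_716H (0.0774).

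Genes of chromatin, imprinting and limb position were also listed. Of 15 measured genes of the DNA methylation machinery, 4 rose and 2 fell, and the list did not pass (adjusted p = 0.281). The maintenance methyltransferase Dnmt1 rose 3.76-fold (11.32 ± 0.20 against 9.41 ± 0.25, SD, n = 3 each), its partner Uhrf1 4.26-fold and the helicase Hells 3.36-fold, and the dioxygenase Tet1 fell 2.59-fold. Among the cultures, Dnmt1, Uhrf1 and Hells were highest in culture 2 (9.70, 8.69 and 8.82), where mitosis genes were also higher. Tet1, which fell in the lines, was highest there too (10.15). The rises were not separated from that of the proliferation genes. Without culture 1, culture 2 or OS_493H, 1 member fell. Of 16 measured imprinted genes, 7 rose and 1 fell (camera adjusted p = 0.038, and adjusted p = 0.444 with an estimated correlation). Ndn, Dlk1 and Peg10 rose 10.8-, 8.10- and 7.90-fold, and Igf2 fell 22.7-fold. This call was lost after quantile normalisation (adjusted p = 0.0774), after median centring (0.0751), among brighter genes (0.139), without OS_716H (0.0585) and with fry (0.0705), and 4 members rose without culture 1 or culture 3. Of 31 hindlimb and Hox genes, 2 rose and 3 fell (adjusted p = 0.745), with Hoxd8 2.49-fold higher and Hoxb4, Hoxb7 and Hoxb3 1.76-, 1.46- and 1.41-fold lower. The calls of Hoxb4 and Hoxb3 were lost on leaving out any 1 culture or OS_716H (adjusted p up to 0.0882 and 0.122). On leaving out any 1 culture, 1 Hox or hindlimb gene rose and 1 fell. Without OS_493H, 1 rose and 5 fell, and without OS_716H, 4 rose and 2 fell.

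The remaining marker lists did not pass the preset test. Of 22 stromal progenitor markers, 7 rose and 5 fell (adjusted p = 0.112), or 10 and 5 adjusted over the list alone. Thy1, Cd34 and endoglin (Eng) rose 26.2-, 19.7- and 7.74-fold, and Nt5e, which encodes CD73, fell 5.50-fold. Without culture 1 or culture 3, 3 of these markers fell. Of 16 endothelial markers only Eng rose (list adjusted p = 0.668), and Tek was 9.05, 6.30 and 7.52 in the lines against a culture mean of 6.38. Without OS_494H, 2 endothelial markers rose, and without OS_493H 1 fell. Of 19 chondrocyte markers, 3 fell (adjusted p = 0.338), with Col10a1, Matn4 and Sox5 10.6-, 1.55- and 1.43-fold lower. Without OS_494H, 2 chondrocyte markers rose. The call of Sox5 was lost on leaving out any 1 culture or OS_493H (adjusted p up to 0.09). Of 21 macrophage and osteoclast markers, 2 rose and 3 fell (adjusted p = 0.797). Acp5 and Cd14 rose 1.81- and 1.44-fold, and cathepsin K (Ctsk) and Atp6v0d2 fell 3.13- and 3.04-fold. The calls of Cd14 and Ctsk were lost without culture 1 (adjusted p = 0.0724 and 0.053), and that of Cd14 also without culture 2 (0.0556) or OS_493H (0.0524), and in each of these fits 1 macrophage marker rose. Of 18 skeletal muscle markers Acta1 rose 1.27-fold (list adjusted p = 0.974), a call lost without culture 1 (adjusted p = 0.0558) or culture 3 (0.0677), and Actc1 differed by 0.36 and did not pass. Without culture 2, 2 muscle markers rose, and without OS_716H 1 fell. No gene of 13 lymphoid and erythroid markers (list adjusted p = 0.62) or of 8 sex-linked genes (0.319) passed. Cd3d and Ighm differed by 0.26 and -0.15. Without OS_493H, the line with Xist, 3 sex-linked genes and their list passed upward (adjusted p = 0.0109).

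**Figure D2:**
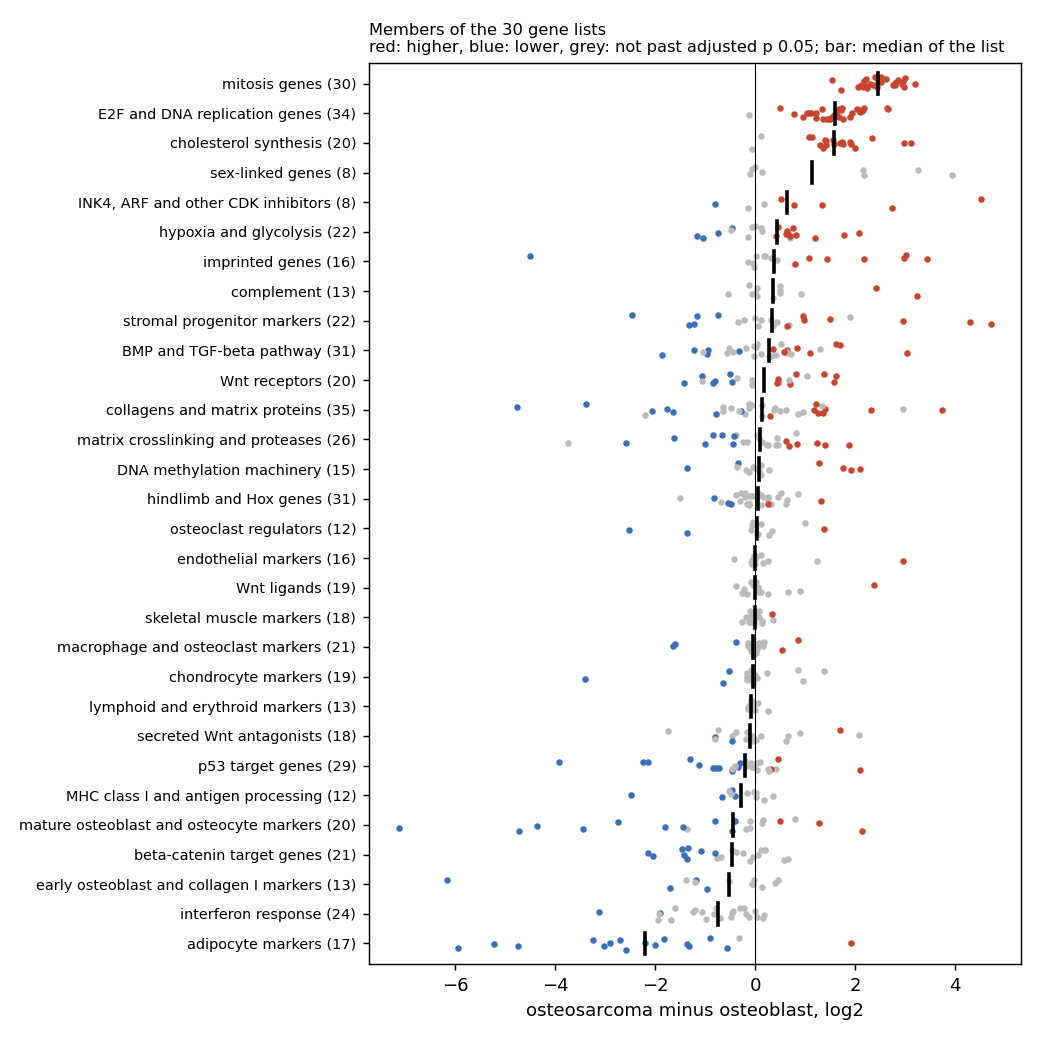
Log2 difference of each measured member of the 30 gene lists, osteosarcoma minus osteoblast, with the number of measured members in brackets. Red and blue points passed the gene-level test upward and downward, grey points did not, and black bars give list medians, of which mitosis genes have the highest median (2.45) and adipocyte markers the lowest (-2.20).

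Members of the interferon response list were higher in OS_493H than in the other lines, by a median of 1.34 log2 units, without a test of single lines. The interferon response list passed downward (camera adjusted p = 0.019, and adjusted p = 0.805 with an estimated correlation), but 2 of its 24 measured members fell and none rose, and 1 fell adjusted over the list alone. The median member was 0.16 log2 units above the culture mean in OS_493H, 0.99 below it in OS_494H (-0.99) and 1.26 below it in OS_716H (-1.26). The antiviral genes Trim30a and Bst2 fell, Trim30a being 10.05 in OS_493H, 7.86 in OS_494H and 6.76 in OS_716H against 11.35 ± 0.33 (SD, n = 3) in the cultures. Without OS_493H, 16 members fell. Without OS_494H or without OS_716H the list did not pass (adjusted p = 0.0808 and 0.16), nor did it with array weights (0.14) or with fry (0.303), and Trim30a did not pass on leaving out any 1 culture or OS_494H (up to 0.0988). Of 12 measured MHC class I and antigen processing genes, 4 fell and none rose (list adjusted p = 0.112), and the median member of OS_493H, OS_494H and OS_716H differed from the other lines by 0.24, -0.18 and -0.11. H2-Q4 fell 5.62-fold, and Tap2, B2m and Nlrc5 1.59-, 1.39- and 1.32-fold. Without culture 1 or culture 3, 2 members fell. The call of B2m was lost without either of these (adjusted p up to 0.0522) and that of Nlrc5 on leaving out any 1 array except OS_716H (up to 0.114). The value of Nlrc5 is that of the brightest of its 19 probe sets (-0.40), and over all 19 the difference was -0.15 to -1.51 (adjusted p = 0.291 and 0.00135 over all probe sets for these extremes). The list passed without OS_493H (0.01), without culture 2 (0.0445) and after quantile normalisation (0.0474).

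The lines, which came from separate tumours, varied more than the cultures, which came from 1 cell line. The SD over the lines exceeded that over the cultures for 13120 genes (65.8%), and the median SD was 0.131 over lines and 0.0917 over cultures. No test was made for single lines, since each is 1 array. The genes furthest from the other lines are ranked within the naming rule, which takes only genes that differ by less than 0.5 between those 2 lines. In OS_493H the genes furthest above the other lines were Xist and the interferon-inducible genes Iigp1 and Ifi205 (10.08 and 9.53 against means of 6.86 and 6.45), and those furthest below were the 3 Y-linked genes. In OS_494H, Lrrc15, Hpgd and Slc6a15 lay 3.15, 2.41 and 2.36 log2 units above the other lines. Slc6a15 was also called higher in the lines as a group (adjusted p = 0.0461), a call lost on leaving out any 1 culture (up to 0.137). Serpina3n, Igfbp4 and Kng2 lay furthest below, Igfbp4 at 8.95, a log2 difference of -4.04 from the mean of the other lines. In OS_716H, the developmental gene Mab21l2 (10.94 against 7.03), fibromodulin (Fmod, 10.93 against 8.22) and Dhdh (9.79 against 7.28) lay furthest above. Klhdc8a, Rgs20 and Itga6 lay 2.33, 2.12 and 2.09 log2 units below (-2.33, -2.12 and -2.09). The Fmod level of OS_716H was close to the culture mean of 11.34 ± 0.56 (SD, n = 3). Among early osteoblast markers the median of OS_716H was 0.45 above the other lines and that of OS_493H was 0.69 below them (-0.69). Among the lines Wif1, Sp7 and Ibsp were highest in OS_716H, at 7.66, 9.04 and 8.20, whereas Phex, Dmp1 and Phospho1 were lowest there, at 6.40, 6.56 and 7.53, and among mature osteoblast markers its median was 0.11 above the other lines.

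**Figure D3:**
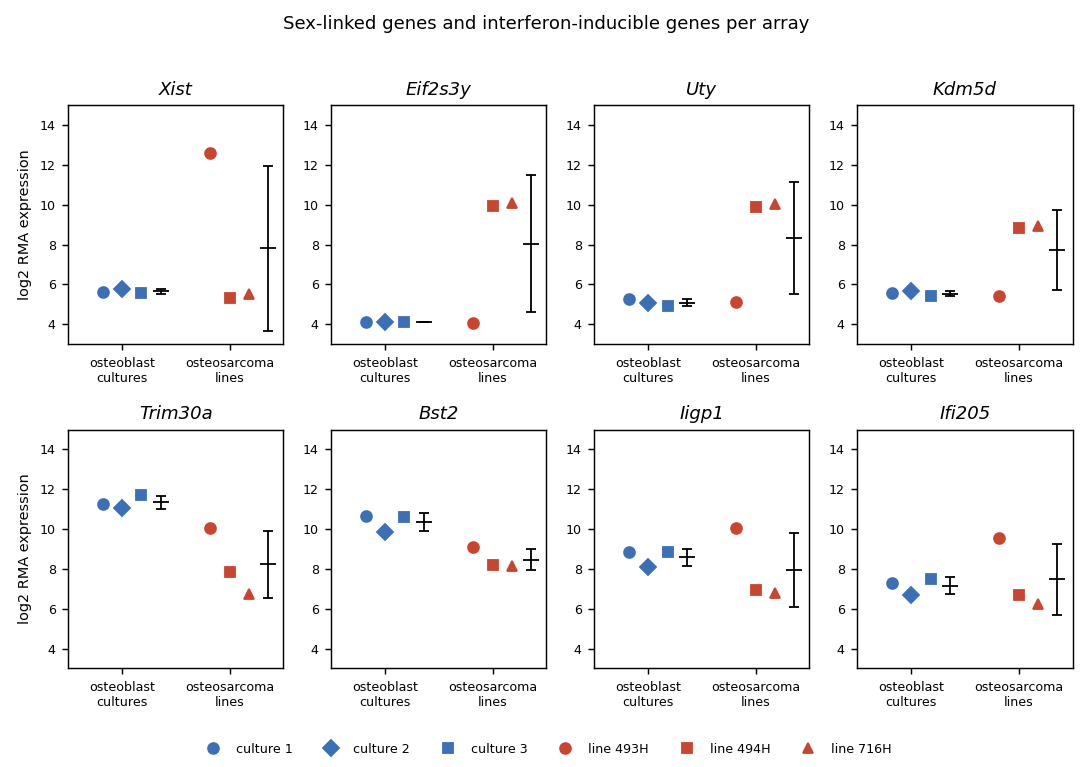
Log2 expression of 4 sex-linked genes (upper row) and 4 interferon-inducible genes (lower row) on each array, with osteoblast cultures in blue, osteosarcoma lines in red, and the mean and SD as bars with whiskers (n = 3). Xist is high in OS_493H (12.62), the Y-linked genes are high in OS_494H and OS_716H, and the interferon-inducible genes are highest among the lines in OS_493H.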

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

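Probe sets that the comparison of genes leaves out also differed between the groups. Of the 12146 probe sets that the probe table does not list, 703 were higher and 1624 lower in the osteosarcoma lines (limma, adjusted p under 0.05), with a largest rise of 4.65 log2 units. Of the 1621 probe sets listed with several gene symbols, 185 were higher and 210 lower, with a largest rise of 3.19. The share called was 19.2% of the unlisted probe sets and 24.4% of those with several symbols, against 24.6% of the genes tested. These probe sets are given because they show a signal in data outside the main measurement. No explanation was tested for them, and groups of 3 samples are too small to look for single outlying samples by their spread.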

How the results depend on the processing

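The mean of cultures 1 and 3 as 1 sample was the setting chosen after the data were seen. Without 1 array, 1533 to 2796 genes were higher and 1211 to 2314 lower. The lowest counts came without culture 1, and without culture 3 they were 1610 and 1350. With the mean of cultures 1 and 3 as 1 sample they were 1606 and 1316, of which 1606 and 1315 were among the genes called from all arrays. Fewer samples enter these fits. All probe sets by ID gave 3566 higher and 4150 lower, at least 2-fold 811 and 561, and adjusted p under 0.01 1394 and 1072, by construction. Median centring gave 3129 higher and 1800 lower, and quantile normalisation 2818 and 2278. The median difference of all genes was -0.02, 0.04 after centring and 0.03 after quantile normalisation. Wif1 was lower under every setting run, with adjusted p from 0.0551 (brighter genes) to 0.184 (without OS_493H) and a difference of -1.09 to -2.10, and it was never called. Among brighter genes, 8408 varied more over lines, since fewer genes enter. Of 30 gene lists, 0 passed with an estimated correlation, where camera's preset gave 9. The estimate was -0.05 for inhibitors of cyclin-dependent kinases, 0.02 for mature osteoblast markers and 0.03 for imprinted genes, against the preset of 0.01. For the other lists called at the preset it was 0.22 to 0.96. A higher correlation therefore does not account for every loss, and the cause was not tested. Other settings gave 7 to 12 lists, and fry 10. Camera was not run with robust moderation. Wif1 set apart, 105 named genes were called, most of them picked for large changes on these same arrays. Of these, 82 kept call and direction under every setting that tested them singly, and 87 under those that leave out no array. The 2-fold, adjusted p under 0.01 and all-probe-set settings were not counted for named genes. Without some array 23 lost the call, 17 lost it with the mean of cultures 1 and 3 as 1 sample, and 0 reversed. Igfbp4, not called from all arrays (-0.75), was 0.60 without OS_494H (adjusted p = 0.0399), the array with its low value, and -1.53 to 0.60 over arrays left out. Over its alternatives its adjusted p was 0.0399 to 0.796. RMA values hold no background level, so signal over background could not be set.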

Other observations

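The tests of culture 2, of line OS_716H and of neighbouring genes were chosen after the values had been seen, and the counts over other splits of the arrays before. The genes in this and the next paragraph that the naming rule does not give were also picked after seeing their values. Dlk1 rose together with neighbours in the same imprinted domain. The long non-coding RNAs Meg3 and Rian were higher in the lines by 2.18 ± 0.46 and 1.44 ± 0.33 log2 units (SE, limma adjusted p = 0.0159 and 0.0207), higher in 3 of 3 lines than in any culture. Rtl1 of that domain differed by -0.19 (adjusted p = 0.294). In the bone phosphoprotein cluster Ibsp and Dmp1 fell strongly, whereas their neighbours Mepe and Dspp were low in both groups (5.29 against 5.47 and 6.81 against 6.86). Lum and Dcn fell together, and their neighbours Kera and Epyc were low in both groups (5.15 against 5.20 and 5.61 against 5.63). Around Cdkn2a, the adjacent Cdkn2b rose and Mtap did not pass (11.36 against 11.49, adjusted p = 0.553).

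Among genes of smooth muscle and actin filaments, of which no list was tested, Tagln was higher by 2.09 ± 0.47, Tpm2 by 1.61 ± 0.23 and Tpm1 by 1.14 ± 0.19 log2 units (SE, adjusted p = 0.0205, 0.00379 and 0.00641). Acta2 (0.67) and Myh11 (0.06) did not pass. Of further genes outside the lists, Ezh2 was higher by 0.91 and Tert by 0.85 (adjusted p = 0.00142 and 0.00459), while Cdk4 differed by -0.08 and did not pass. Mdm2, a p53 target and p53 ligase gene, was 12.18 in OS_493H against 10.19 in OS_494H, 9.91 in OS_716H and 10.92 ± 0.03 (SD, n = 3) in the cultures. Slc35e3, its neighbour, was 10.67, 9.86 and 9.54 in those lines, whereas Nup107 and Rap1b nearby were within 0.3 log2 units of each other over the lines.

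The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Each split but the real one mixes the groups, which keeps part of their difference and adds to the spread. The counts below therefore do not show what chance gives. The real split gave 4896 changed genes, and the highest of the other splits gave 0 (1 of 10 splits as large). For the gene lists the real split gave 9 called lists at the preset correlation, and the highest of the other splits gave 10 (6 of 10 splits as large).

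Osteoblast culture 2 stood apart from cultures 1 and 3. It had 120 genes more than 1 log2 unit above their mean and 28 as far below, with mitosis genes higher by a median of 1.07 and Wif1 higher by 2.00. Among the other lists the median was also higher for cholesterol synthesis (0.54), early osteoblast markers (0.52), beta-catenin targets (0.40) and replication genes (0.38), and lower for interferon response (-0.49) and adipocyte markers (-0.34). RNA of osteosarcoma cells in this sample would give the same share from every gene that is high in the lines. Listed replication and mitosis genes left out, 52 genes were at least 8-fold higher in the lines than in cultures 1 and 3. They implied a median share of 5.57% (quartiles 0.408% and 10.4%), with Thy1 at 0.0715% and Cdkn2a at 0.409%. Mitosis genes implied 17.4% (quartiles 13.5% and 21.3%), which argues against such RNA as the whole of their rise. A smaller share beside another difference was not tested. Of the 120 genes higher in culture 2, 64 were called higher in the lines in the fit without culture 2. In that fit 16 were called lower and 40 were not called. An intensity-dependent shift of the array would move other genes of the same level, but the highest of 10000 random lists matched on mean level reached 0.18 against 1.07 for the mitosis genes. The titles set the cultures apart as Ex1, Ex2 and Ex3, without saying what differed, so a difference between separate experiments stays open and no biological explanation was tested.

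The array labelled OS_716H, female, carried Y-linked transcripts and no Xist signal. An exchange of labels with OS_494H would need OS_494H to carry Xist, but its value lay 7.31 log2 units below OS_493H (-7.31). A minor share of male RNA in a female sample would leave Xist near the level of OS_493H, but OS_716H lay 7.11 below it (-7.11). The mean of the 3 Y-linked genes in OS_716H was 0.13 above that of OS_494H, as a wrong sex label or a line from a male animal would give, and these cannot be separated with these data. Loss of Xist expression alone would not bring Y-linked transcripts. The mouse from which the line came stays open, and the comparison of the groups does not use sex.

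A run of 15 neighbouring genes from Tenm3 to Clcn3 was higher in OS_494H than in the mean of the other lines, by a median of 0.59 log2 units, and 13 of the 15 genes were higher. The 12 runs looked at were the highest and lowest of each array, over 11195 genes ordered by their position in GRCm38.p6. Only genes with a mean above the median of all values were ordered, so dimmer genes lying between members of a run were left out. Shuffling the order 1000 times gave an unadjusted p of 9.99e-04 for this run, the smallest that the shuffles could give. Adjusted over the 12 runs it was 0.012, against a chance order of genes. The run holds Hpgd, Sap30 and Hmgb2. A gain of this region in OS_494H may be a hypothesis, but neighbouring genes can also share regulation. Lower runs past the same threshold were found in OS_493H (Pdgfd to Cep57, -0.31), in OS_716H (Cavin4 to Ctnnal1, -0.51) and in culture 1, which is not a tumour line (Zkscan8 to H4c3, -0.23), each with an adjusted p of 0.024. DNA copy number was not analysed here.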
